A study of Mus musculus with 11 samples.

How the data were processed

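RNA was measured in vascular fragments of the ipsilateral hemisphere of adult male C57BL/6 mice after MCAO, on 11 Affymetrix arrays. Per the submitters' processing notes, 10 ng of total RNA was amplified with the NuGEN Ovation Pico WTA V2 system and labelled with the Encore Biotin module. The type of array, the genome build and the versions of the submitters' tools are not given in the sources used here. The deposited values are log2 RMA signals of probe sets, which the authors made with Affymetrix Expression Console, and the notes also name limma. They were not normalized again. The deposited workbook and series matrix table held the same values (largest gap 0), so their exchange as an alternative tested nothing. The authors' deposited log2 differences between imatinib and PBS were within 1e-10 of the differences of the group means in 33793 probe sets. By those columns 44 probe sets differed at least 2-fold at 3 h (31 higher, 13 lower) and 29 at 24 h (9 higher, 20 lower). The medians of the arrays lay between 5.17 and 5.25 and no depth per array is given.

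Samples were grouped by treatment and time per the labels. Of 33793 probe sets, 1591 without a gene symbol, 128 with several symbols and 14 with a symbol turned into a date were left out. For the 730 genes with several probe sets, the probe set with the highest mean was kept, which left 30790 genes. Of their symbols 25411 were found in a RefSeq table, 1333 as synonyms there, and 4046 were not found. Predicted and small RNA genes numbered 11078 and were tested with the others.

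The comparisons were made in limma 3.58.1 (R 4.3.3) with 1 mean for each of the 4 groups fitted on all 11 arrays. The 5 contrasts were imatinib against PBS at 3 h and at 24 h, 24 h against 3 h in PBS and in imatinib, and the interaction, which is the imatinib difference at 24 h minus that at 3 h. Variances were moderated by empirical Bayes (residual degrees of freedom 7, prior degrees of freedom 4.37, prior SD 0.154) and p-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. Figures were drawn with matplotlib 3.10.9.

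Lists of genes were written from general knowledge, 27 of pathways and 16 of cell types. The pathway lists were imatinib target kinases, PDGF ligands and receptors, tight and adherens junctions, blood-brain barrier transporters, Wnt and barrier transcriptional regulators, endothelial activation and leukocyte adhesion, caveolae, cytokines and chemokines, NF-kappa-B feedback, immediate early genes, heat shock, unfolded protein response, hypoxia, oxidative stress, coagulation, matrix proteases, basement membrane, TGF-beta response, angiogenesis, interferon response, complement, cell cycle, p53 response, glucocorticoid response, cholesterol synthesis, oxidative phosphorylation and glycolysis. The cell type lists were endothelial cells, pericytes, smooth muscle, perivascular fibroblasts, astrocytes, neurons, oligodendrocytes, oligodendrocyte precursors, microglia, border macrophages, monocytes, neutrophils, T and NK cells, B cells, erythroid cells and choroid plexus. They held 718 entries, 12 of which matched none of the genes tested, among them Cxcl2 and 4 haemoglobin genes, and had 7 to 33 genes measured. Each list was compared with the other genes by camera in limma with a preset correlation between genes of 0.01, and again with a correlation estimated from the data, with Benjamini-Hochberg adjustment over the 43 lists. The fry test of limma asked whether a list's genes move on balance in 1 direction, and its mixed version whether they move in either direction. Fry's mixed version called 2 lists at 3 h, 7 at 24 h, 42 over time in PBS, 38 over time in imatinib and 2 in the interaction. List scores are means over the genes of a list on each array and were compared by exact permutation.

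Genes were named by a rule. For each contrast it took the 8 largest rises and 8 largest falls past the threshold whose groups do not overlap. Where fewer than 5 genes passed in a direction, it took the 5 with the smallest unadjusted p. For each list it allowed up to 2 genes per direction with the largest change past the threshold, or else the gene with the smallest p. Pdgfra, Pdgfrb, Kit, Abl1, Abl2, Csf1r, Ddr1, Ddr2, Pdgfc and Plat were always reported. Predicted genes, small RNAs and olfactory receptors were counted but not named for size, and numbered 622 of the genes past the threshold over time in PBS and 543 in imatinib. The genes called in opposite directions over time were named after their values were seen.

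The pipeline was tested on simulated data with 200 of 30790 genes changed, 10 simulations for each setting. The shares recovered depend on that number, and no smaller number was simulated. For imatinib at 24 h it recovered 25% of 1.5-fold, 93.5% of 2-fold and 99.85% of 4-fold changes, with no wrong signs, and for the time course in PBS 25%, 93.75% and 99.85%. Camera with the preset recovered 98% of lists shifted by 0.25 and called 0.4 of 29 unshifted lists on average, on genes simulated as independent, which real genes are not.

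The alternatives, applied 1 at a time, were filters on dim genes (25th percentile or median), centring of arrays on their medians, cyclic loess, only the groups compared, a trended and robust variance, array weights, each array left out, a replicate block, all probe sets, other thresholds and the estimated correlation. A fit without PBS 3 h replicate 1 and PBS 24 h replicate 3 together, and a treatment effect common to both times, were added after the data were seen.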

Results

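The arrays measured RNA of vascular fragments, pieces of blood vessel isolated from the brain hemisphere on the side of a middle cerebral artery occlusion (MCAO), an experimental stroke made by blocking a main artery of the forebrain. The mice were adult C57BL/6 males given imatinib, an inhibitor of tyrosine kinases that include ABL, KIT and the receptors for platelet-derived growth factor (PDGF), or phosphate-buffered saline (PBS). Vessels were taken 3 h or 24 h after MCAO. The 11 arrays formed 4 groups, PBS at 3 h (n = 3), imatinib at 3 h (n = 2), PBS at 24 h (n = 3) and imatinib at 24 h (n = 3). The numbers of the deposited columns skip 6, between the imatinib 3 h and the PBS 24 h arrays, and no array of that number was analysed here. Mice sampled at 3 h had been treated 3 times and mice sampled at 24 h 4 times, so the number of treatments went with the time. Vessels without occlusion were not analysed here. Values are log2 array signals, and the number of arrays limits their precision. The labels do not say whether the replicates were separate animals, so each p-value measures only the spread between these samples.

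Time separated the arrays more than treatment did. The first principal component held 50.2% of the variance and its scores averaged -34.5 ± 2.36 (SD) in PBS at 3 h, -37.6 ± 0.422 in imatinib at 3 h, 33.1 ± 4.801 in PBS at 24 h and 26.6 ± 0.521 in imatinib at 24 h. The second component held 7.99% of the variance and set apart PBS 3 h replicate 1, with a score of 35.9. Across genes, Pearson's r was 0.988 to 0.993 between arrays of the same group, 0.987 to 0.992 between treatments at the same time and 0.972 to 0.9803 between times.

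**Figure D1:**
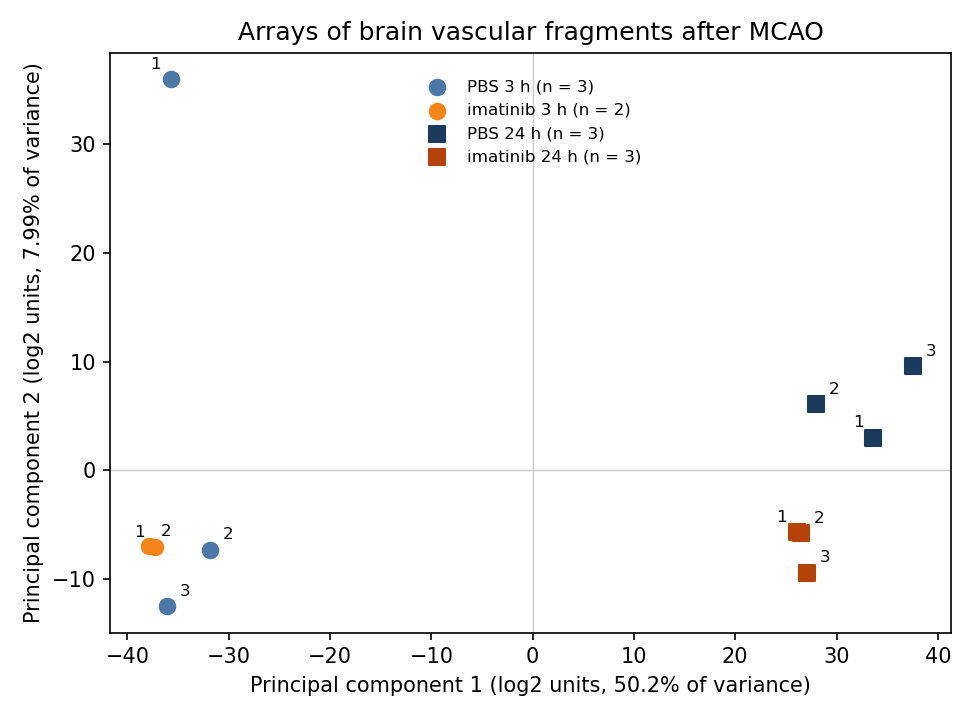
Scores of the 11 arrays on the first 2 principal components of the log2 values (axes in log2 units); each point is an array, numbered by replicate, circles are 3 h and squares 24 h. The 3 h arrays lie below 0 and the 24 h arrays above 0 on component 1 (50.2% of the variance), and PBS 3 h replicate 1 lies alone at 35.9 on component 2.

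The first comparison asked how the vessels of PBS-treated mice changed between 3 h and 24 h after MCAO. At 24 h, genes of macrophages and chemokines were among the largest rises, and genes induced by glucocorticoids were among the largest falls. Cxcl3, a chemokine that attracts neutrophils, rose from 3.57 ± 0.17 to 9.16 ± 1.14 (mean log2 signal ± SD, n = 3 in each group). Its 3 h signals lay below the 25th percentile of those arrays (3.90 to 3.92), so no fold is given for it. Msr1, a scavenger receptor of macrophages, rose from 5.18 ± 0.51 to 10.76 ± 0.23, a 47.7-fold difference. Zbtb16, a transcription factor induced by glucocorticoids, fell from 9.93 ± 0.21 to 6.81 ± 0.44. Plat, which encodes tissue plasminogen activator, a protease that also activates the PDGF-C ligand, fell from 11.27 ± 0.15 to 9.47 ± 0.29.

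Of 30790 genes tested with limma, 5119 passed a Benjamini-Hochberg adjusted p of 0.05, 2877 of them higher and 2242 lower at 24 h. At least 2-fold changes were found in 881 of them (557 higher, 324 lower) and at least 4-fold changes in 108 (88 higher, 20 lower). The groups did not overlap in 29.9% of all genes, where chance gives 10%. By the naming rule, each gene named for its size here had all 3 arrays of 1 time above all 3 arrays of the other. Besides Cxcl3 (adjusted p = 1.78e-05 in limma) and Msr1 (log2 difference 5.57 ± 0.21 SE, adjusted p = 2.39e-07), large rises were in Chil3, a macrophage lectin (4.40 ± 0.37, adjusted p = 1.96e-05), and Spp1, osteopontin (4.27 ± 0.14, adjusted p = 9.93e-08). AA467197 (4.22 ± 0.24), the acute phase protein gene Saa3 (4.12 ± 0.42), the inhibitory leukocyte receptor gene Lilrb4 (4.09 ± 0.30) and the vascular peptide gene Apln (4.05 ± 0.27) followed. The Chil3 signal in PBS 3 h replicate 3 (3.86) lay below the 25th percentile of that array (3.91), so the size of its rise is uncertain. Hamp, which encodes the iron hormone hepcidin, fell (-3.69 ± 0.74, adjusted p = 0.00481 in limma) to 24 h signals below the 25th percentile of those arrays (3.87 to 3.88), so the size of its fall is uncertain. Large falls were also in Serpina3f (-3.40 ± 0.28), the p53 target Trp53inp1 (-3.19 ± 0.22) and Zbtb16 (-3.12 ± 0.25, adjusted p = 1.3e-05). Rasd1, a dexamethasone-induced RAS gene (-2.82 ± 0.26), Asb4 (-2.76 ± 0.15), the immediate early receptor gene Nr4a3 (-2.64 ± 0.20) and the mitotic kinesin gene Kif23 (-2.53 ± 0.15) were next.

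**Figure D2:**
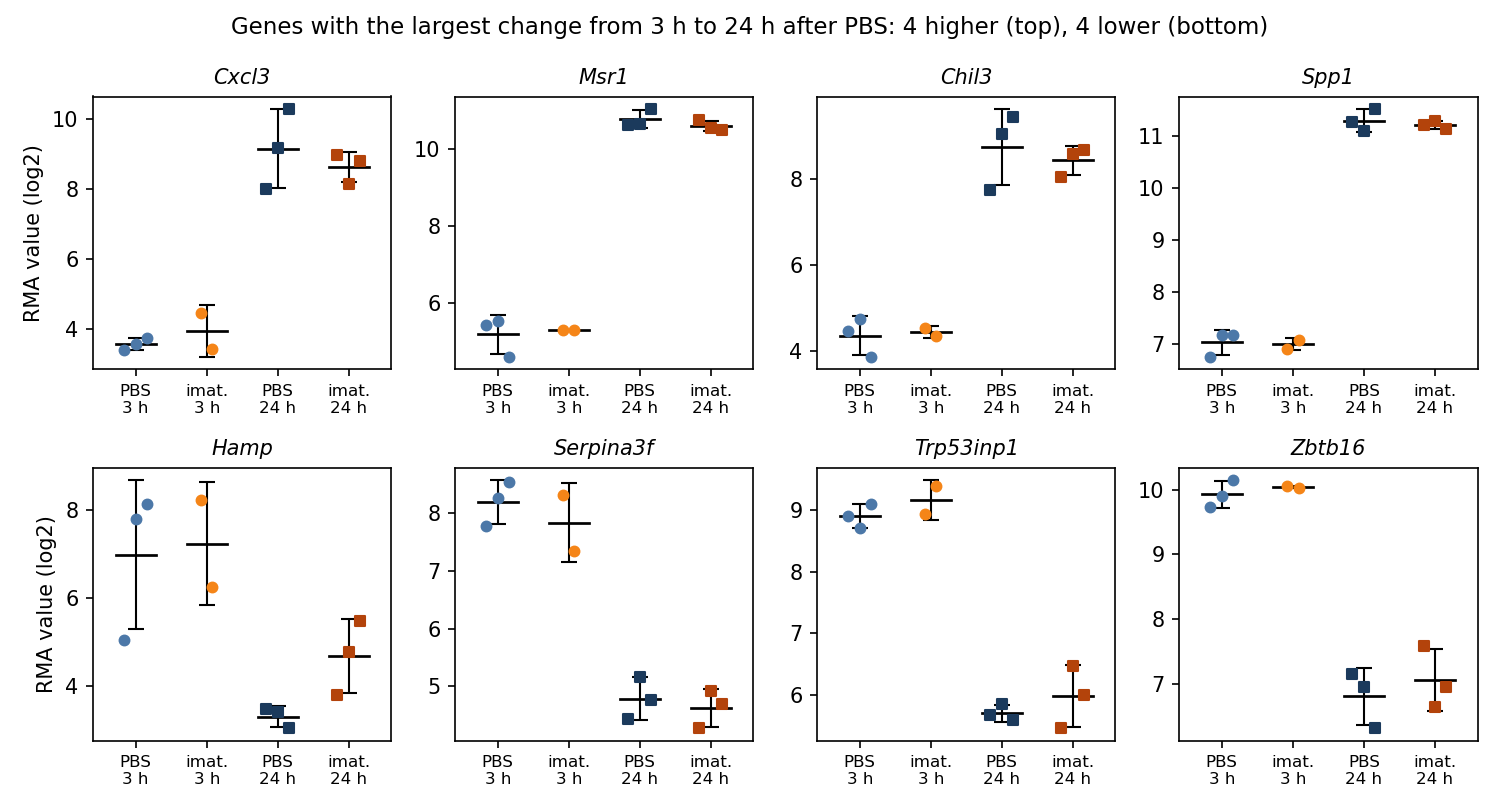
RMA values (log2) of each array for the 4 genes with the largest fitted rise (top) and the 4 with the largest fitted fall (bottom) from 3 h to 24 h after PBS; points are arrays, lines the group mean and bars 1 SD (n = 3, 2, 3 and 3). Cxcl3 averages 3.57 in PBS at 3 h and 9.16 in PBS at 24 h, and Zbtb16 averages 9.93 and 6.81.

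Gene lists, fixed before the data were examined like the tests and the rule for naming genes, were compared with all other genes by camera. With its preset correlation of 0.01, 24 of 43 lists passed an adjusted p of 0.05 in this comparison, 13 higher and 11 lower at 24 h. No list passed with an estimated correlation (smallest adjusted p = 0.0716), and fry, which asks whether a list's own genes move on balance in 1 direction and does not compare them with other genes, called 29. The scores of 23 of the 24 lists, each the mean of a list's genes on an array, did not overlap between the times. The exact permutation p of each of these is 0.1, two-sided, the smallest that 3 against 3 arrays allow.

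Inflammatory lists were higher at 24 h. Of 26 cytokine and chemokine genes 17 rose, 2 fell and 7 did not pass (20 and 2 adjusted over the list alone), with a median of 1.12 and an adjusted p of 3.46e-13 (adjusted p = 0.0716 with an estimated correlation). Cxcl12, a chemokine of vessel walls (-1.03 ± 0.15), and the growth factor gene Csf1 (-0.35 ± 0.10, adjusted p = 0.041 in limma) fell. Csf1 passed without PBS 3 h replicate 1 but did not pass without any 1 of the other 10 arrays (-0.38 to -0.27). Of 11 monocyte genes 9 rose and none fell (9 adjusted over the list alone), with a median of 2.20 (adjusted p = 1.26e-11 with the preset and adjusted p = 0.0716 with an estimated correlation). Neutrophil genes had a median of 0.60 and 6 of 15 rose (7 adjusted over the list alone), among them S100a8 (2.06 ± 0.46) and the chemokine receptor gene Cxcr2 (1.96 ± 0.31). The adjusted p was 0.0054 (adjusted p = 0.317 with an estimated correlation). Border macrophage genes, 4 of 8 of which rose (4 adjusted over the list alone), had a median of 0.41, with F13a1 at 1.68 ± 0.18 and Mrc1 at 1.26 ± 0.20. The list passed (adjusted p = 0.00662 with the preset and 0.268 with an estimated correlation). Complement genes had a median of 0.31, with 7 of 14 higher, C3 among them (2.22 ± 0.24), and Cd59a, an inhibitor of the membrane attack complex, lower (-1.59 ± 0.14; adjusted p = 0.00981 with the preset and adjusted p = 0.219 with an estimated correlation). The counts for complement adjusted over the list alone were 7 and 1.

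Genes of endothelial activation and leukocyte adhesion had a median of 0.55, with 9 of 18 higher and 2 lower (10 and 4 adjusted over the list alone). The integrin gene Itgal (1.54 ± 0.21) and Cd74 (1.42 ± 0.23) rose and Selplg, a selectin ligand, fell (-0.89 ± 0.16). The list passed at an adjusted p of 0.00662 (adjusted p = 0.246 with an estimated correlation). Matrix proteases and their inhibitors had a median of 0.29, with 7 of 20 higher and 2 lower (8 and 2 adjusted over the list alone; adjusted p = 0.00981 with the preset and adjusted p = 0.211 with an estimated correlation). Adam8 (2.73 ± 0.18) and Timp1 (2.62 ± 0.30) rose, and the protease inhibitor genes Timp3 (-1.05 ± 0.09) and Timp4 (-0.80 ± 0.13) fell.

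Lists of proliferation and metabolism were also higher. Of 24 cell cycle genes 14 rose and none fell (19 adjusted over the list alone), led by the replication licensing genes Mcm5 (2.44 ± 0.15) and Mcm2 (1.76 ± 0.12). The median was 0.67 (adjusted p = 3.46e-13 with the preset and 0.0716 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.25, and all 24 lay above 0, 8 of them past the threshold (14 adjusted over the list alone; adjusted p = 3.04e-07 with the preset and adjusted p = 0.151 with an estimated correlation). Cholesterol synthesis genes had a median of 0.32 with 8 of 18 higher (9 adjusted over the list alone), Sqle (1.10 ± 0.16) and Fdps (0.81 ± 0.12) among them (adjusted p = 5.9e-05 with the preset and adjusted p = 0.246 with an estimated correlation). Glycolysis genes had a median of 0.19 with 7 of 16 higher, Pgk1 among them (1.15 ± 0.12), and 2 lower (7 and 3 adjusted over the list alone). Its adjusted p was 0.0383 (adjusted p = 0.36 with an estimated correlation). In camera the call was lost without PBS 3 h replicate 1 (median 0.16, adjusted p = 0.0747), PBS 3 h replicate 2 (0.14, 0.074) or PBS 24 h replicate 3 (0.13, 0.0992). The median was 0.28 without PBS 3 h replicate 3, with the call kept. In the unfolded protein response list 8 of 19 genes rose, such as the chaperone genes Sdf2l1 (1.88 ± 0.19) and Pdia6 (1.17 ± 0.11), and 3 fell, such as Ddit4 (-1.68 ± 0.27; the same counts adjusted over the list alone). The test called it higher (adjusted p = 0.0112; adjusted p = 0.268 with an estimated correlation) with a mean of 0.31 but a median of -0.01, which was 0.08 without PBS 3 h replicate 3 and 0.02 without PBS 24 h replicate 1.

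The glucocorticoid, immediate early, p53 and TGF-beta lists were lower at 24 h. Of 15 glucocorticoid response genes 14 fell (14 adjusted over the list alone), with a median of -1.02 and Pdk4, a brake on glucose oxidation, at -1.82 ± 0.23 (adjusted p = 3.46e-13 with the preset and adjusted p = 0.0716 with an estimated correlation). Of 33 immediate early genes 17 fell, Nr4a1 among them (-1.82 ± 0.25), and the growth regulator Myc (1.10 ± 0.13) and Fosl1 (0.81 ± 0.17) rose (18 and 2 adjusted over the list alone). Fosl1 did not pass without both PBS 3 h replicate 1 and PBS 24 h replicate 3 (0.76, adjusted p = 0.0647 in limma). The median of the list was -0.49 (adjusted p = 2.83e-07 with the preset and adjusted p = 0.246 with an estimated correlation). The p53 response list had a median of -0.41, with 9 of 19 lower, the death receptor gene Fas among them (-1.71 ± 0.18), and 4 higher, Bax among them (0.76 ± 0.11; 11 and 4 adjusted over the list alone). It passed at an adjusted p of 0.0121 (adjusted p = 0.151 with an estimated correlation). TGF-beta response genes had a median of -0.37, with 9 of 22 lower, such as the receptor gene Tgfbr1 (-1.14 ± 0.14) and Ctgf (-1.10 ± 0.20), and 2 higher, Tgfbi (2.89 ± 0.20) and Inhba (1.03 ± 0.30; 10 and 2 adjusted over the list alone). Inhba did not pass in limma without PBS 3 h replicates 1 (1.03) or 2 (0.90) or PBS 24 h replicates 1 (1.09) or 3 (0.73). The adjusted p was 0.00171 (adjusted p = 0.0716 with an estimated correlation).

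Vessel wall and barrier lists were lower at 24 h. Among 20 Wnt and barrier transcriptional regulators 15 fell and none rose (17 adjusted over the list alone), with the Norrin receptor gene Fzd4 at -1.52 ± 0.17 and Sox7 at -1.25 ± 0.22. The median was -0.59 (adjusted p = 4.56e-11 with the preset and 0.106 with an estimated correlation). Of 17 blood-brain barrier transporters 11 fell (13 adjusted over the list alone), including the efflux pump gene Abcc4 (-1.50 ± 0.18) and the iron exporter gene Slc40a1 (-1.22 ± 0.09). Their median was -0.64 (adjusted p = 2.26e-08 with the preset and 0.161 with an estimated correlation). Endothelial markers had a median of -0.44, with 10 of 18 lower (13 adjusted over the list alone), Ly6c1 (-1.18 ± 0.15) and Pltp (-1.02 ± 0.13) among them. They passed (adjusted p = 2.19e-07 with the preset and 0.211 with an estimated correlation). Tight and adherens junction genes had a median of -0.40, with 10 of 17 lower, Jam2 (-0.70 ± 0.11) and occludin, Ocln (-0.67 ± 0.12), among them (12 lower and 1 higher adjusted over the list alone). It passed (adjusted p = 1.56e-05 with the preset and adjusted p = 0.151 with an estimated correlation). Of 13 pericyte markers 10 fell (11 adjusted over the list alone), Atp13a5 (-0.95 ± 0.19) and Higd1b (-0.93 ± 0.13) among them, with a median of -0.67. They passed (adjusted p = 3.25e-07 with the preset and 0.219 with an estimated correlation).

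Other cell type markers moved beside these lists. Vascular smooth muscle markers had a median of -0.49, with 3 of 12 lower, such as Myl9 (-0.98 ± 0.16), in both counts. The call (adjusted p = 0.00258 with the preset and adjusted p = 0.409 with an estimated correlation) stood without each array, but the median was -0.22 without PBS 24 h replicate 3, -0.76 without PBS 3 h replicate 2 and -0.77 without PBS 24 h replicate 2. Astrocyte markers had a median of -0.53. Of 13 genes 8 fell, the glutamate transporter gene Slc1a3 among them (-0.94 ± 0.20), and Gfap, the intermediate filament of reactive astrocytes, rose (1.37 ± 0.23; 11 and 1 adjusted over the list alone). The list passed (adjusted p = 0.00103 with the preset and 0.282 with an estimated correlation). Erythroid markers were higher, with a median of 0.29 and 3 of 7 past the threshold, the haemoglobin genes Hbb-b2 (0.75 ± 0.14) and Hba-a2 (0.75 ± 0.16) among them (4 adjusted over the list alone). Their adjusted p was 0.0194 (adjusted p = 0.256 with an estimated correlation), lost without PBS 3 h replicate 3 (adjusted p = 0.0556) or PBS 24 h replicate 3 (0.06).

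The other 19 lists did not pass. Several held strong changes in both directions. In the hypoxia list 5 of 23 genes rose, Apln among them, and 8 fell, Ndrg1 among them (-2.13 ± 0.13). In the coagulation list 7 of 19 rose, such as Thbs1 (2.01 ± 0.26), and 5 fell, such as Thbd, thrombomodulin (-1.09 ± 0.11). In the angiogenesis list 6 of 25 rose, such as Angpt2 (1.34 ± 0.22), and 5 fell. Their medians were -0.08, 0.18 and 0.07. Heat shock genes (-0.03; 3 of 15 higher, 5 lower) rose for the mitochondrial chaperone genes Hspd1 (0.97 ± 0.13) and Hspe1 (0.85 ± 0.14) and fell for Hspa1b (-1.68 ± 0.28). The medians of the remaining lists were 0.12 for oxidative stress, 0.10 for T and NK cells, 0.08 for B cells, 0.01 for NF-kappa-B feedback and acute phase (4 higher, 4 lower), -0.03 for microglia, -0.03 for basement membrane, -0.06 for neurons, -0.10 for perivascular fibroblasts and -0.11 for oligodendrocyte precursors. They were -0.12 for interferon response, -0.13 for caveolae, -0.14 for oligodendrocytes, -0.16 for imatinib target kinases, -0.17 for PDGF ligands and receptors and -0.36 for choroid plexus. In the oxidative stress, interferon and kinase lists the median, the mean and the test did not share a sign. Among the kinases that imatinib inhibits, Kit rose (1.57 ± 0.33, adjusted p = 0.00649 in limma) and Pdgfrb, the pericyte PDGF receptor, fell (-0.60 ± 0.17, adjusted p = 0.0312). Kit did not pass without both PBS 3 h replicate 1 and PBS 24 h replicate 3 (1.39, adjusted p = 0.0782 in limma). Pdgfrb did not pass in limma without PBS 3 h replicate 2 (-0.38, adjusted p = 0.0709) or PBS 24 h replicates 1 (-0.64, 0.0614), 2 (-0.52, 0.110) or 3 (-0.65, 0.0564). The values in limma were -0.41 ± 0.17 for Pdgfra (adjusted p = 0.132), -0.30 for Abl2 (-0.38 and past the threshold without PBS 3 h replicate 1, adjusted p = 0.0427), -0.23 for Abl1, -0.17 for Csf1r, -0.16 for Ddr2, -0.02 for Ddr1 and 0.02 for the ligand gene Pdgfc, none past the threshold on all arrays. Plat fell (-1.80 ± 0.24, adjusted p = 0.000435 in limma).

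**Figure D3:**
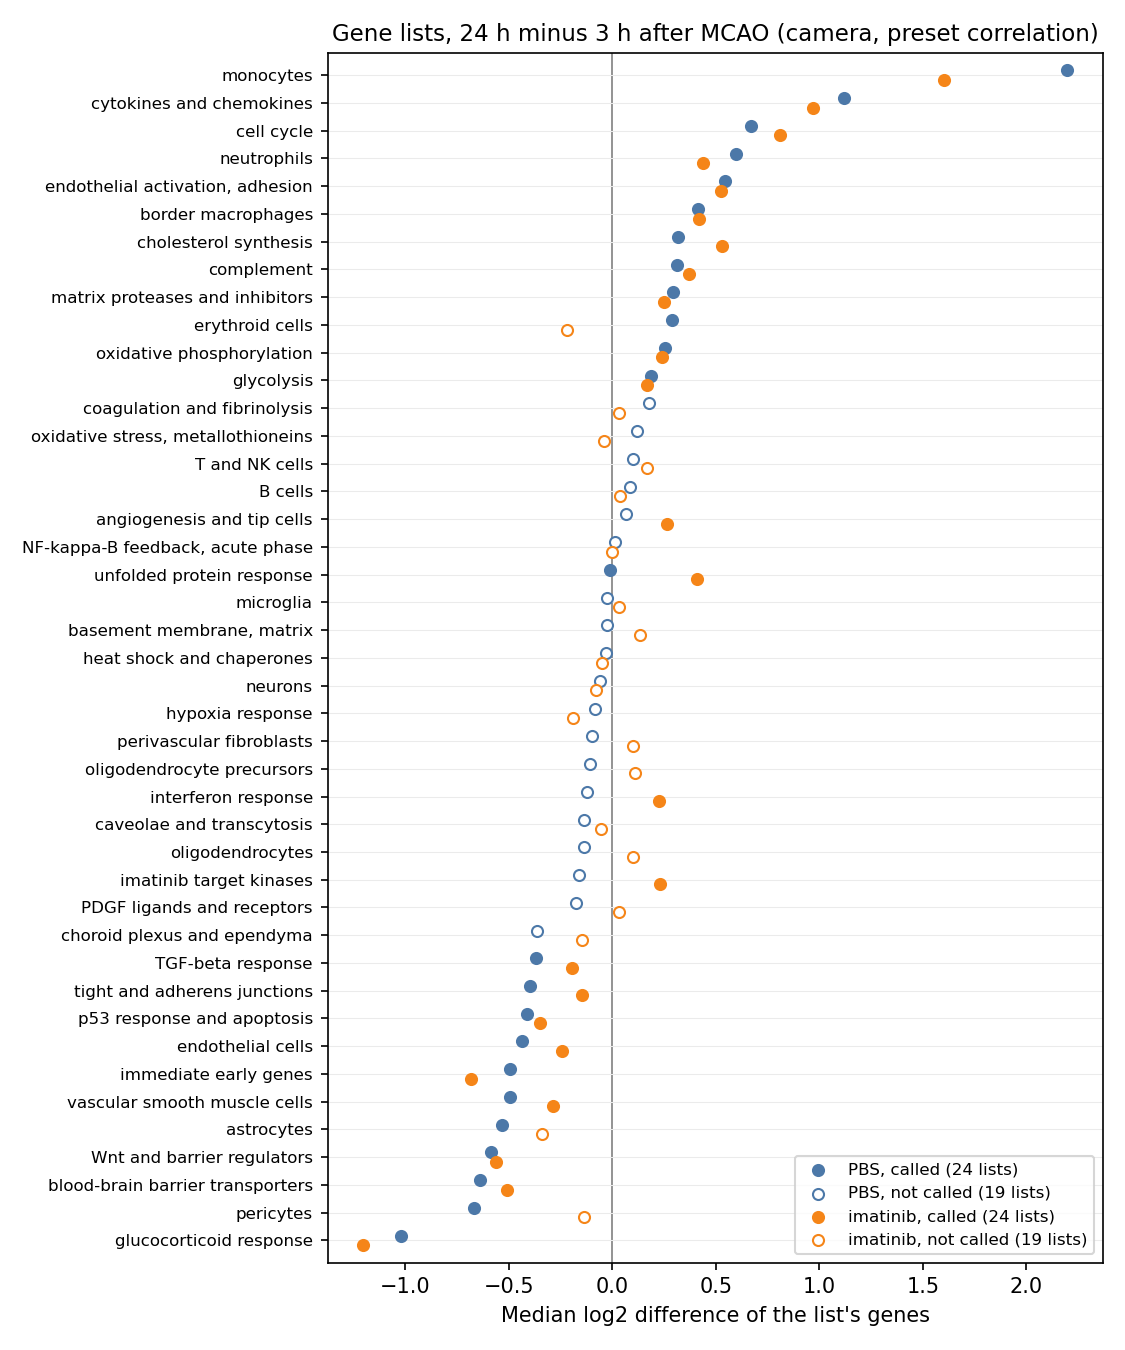
Median log2 difference (24 h minus 3 h) of the genes in each of 43 lists, in PBS (blue) and imatinib (orange); filled points passed camera at an adjusted p of 0.05 with the preset correlation, and none passed with an estimated correlation. The monocyte list has the highest median (2.20 and 1.60) and the glucocorticoid response list the lowest (-1.02 and -1.20).

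The time course with imatinib compared 3 arrays at 24 h with 2 at 3 h. Much of the change seen after PBS was present here too: Msr1 rose by 5.29 ± 0.24 (log2 difference ± SE, adjusted p = 1.29e-06 in limma), Saa3 by 4.42 ± 0.47 and the monocyte chemokine gene Ccl12 by 4.34 ± 0.20. Cxcl3 rose from 3.93 ± 0.74 (SD), with 1 of 2 arrays below the 25th percentile of its values, to 8.64 ± 0.42 (adjusted p = 0.000197 in limma). Spp1 (4.21 ± 0.16), Apln (4.02 ± 0.31), Chil3 (4.00 ± 0.41) and Lilrb4 (3.91 ± 0.33) completed the 8 largest rises. The largest falls were in Serpina3f (-3.21 ± 0.31), Trp53inp1 (-3.18 ± 0.25), Zbtb16 (-2.98 ± 0.27), Nr4a3 (-2.98 ± 0.23), Doc2b (-2.81 ± 0.15), Rasd1 (-2.49 ± 0.29), Asb4 (-2.41 ± 0.17) and Upk1b (-2.40 ± 0.30). In each of these genes the arrays of both times did not overlap. In limma with the Benjamini-Hochberg correction 4027 genes passed, 2389 higher and 1638 lower at 24 h. Of these 815 changed at least 2-fold (503 higher, 312 lower) and 93 at least 4-fold (69 higher, 24 lower), and the groups did not overlap in 42.3% of genes, where chance gives 20%. The count was 2276 without imatinib 3 h replicate 1 and 2274 without replicate 2, since 1 array then stands for the group.

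Both time courses shared 1945 rises and 1166 falls, where independent calls would share 223 and 119. Across genes the changes correlated with a Pearson's r of 0.790 and a Spearman's rho of 0.586, and genes are not independent replicates. Only 6 genes passed in opposite directions. Hba-a2, a haemoglobin chain, rose after PBS (0.75 ± 0.16) and fell after imatinib (-0.59 ± 0.17), and Arnt2, a bHLH-PAS transcription factor, fell after PBS (-0.49, adjusted p = 0.0118 in limma) and rose after imatinib (0.64, adjusted p = 0.00687). The fall of Hba-a2 did not pass in limma without PBS 3 h replicate 2 (-0.59, adjusted p = 0.0559), imatinib 3 h replicates 1 (-0.70, 0.0926) or 2 (-0.48, 0.240), PBS 24 h replicate 2 (-0.59, 0.0622) or imatinib 24 h replicates 1 (-0.54, 0.126) or 2 (-0.53, 0.132). The others were Mir5103, Gm25272, Cyp2d13 and Olfr116, and no gene of the 6 passed the test of the difference itself (smallest adjusted p = 0.371 in limma).

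With imatinib 24 lists passed camera with the preset, 15 higher and 9 lower at 24 h, none with an estimated correlation (smallest adjusted p = 0.0612) and 22 with fry. The scores of all 24 did not overlap between the times. Among the higher lists, cytokines and chemokines had a median of 0.97 and 16 of 26 genes rose and 1 fell (adjusted p = 0.102 with an estimated correlation), and monocytes had a median of 1.60 and 9 of 11 rose (adjusted p = 0.11 with an estimated correlation). In the cell cycle list 16 of 24 rose, with a median of 0.81 and Mcm5 at 2.09 ± 0.17 (adjusted p = 2.08e-14 with the preset and adjusted p = 0.0612 with an estimated correlation). Border macrophages had a median of 0.42 and 4 of 8 rose (adjusted p = 0.191 with an estimated correlation; the median was 0.64 without imatinib 3 h replicate 2). Cholesterol synthesis (0.53, 9 of 18 rose; adjusted p = 0.185 with an estimated correlation), oxidative phosphorylation (0.24, 7 of 24; adjusted p = 0.179) and glycolysis (0.17, 5 of 16, with 2 lower; adjusted p = 0.362) were higher. Complement had a median of 0.37 with 5 of 14 higher and 1 lower, matrix proteases 0.25 with 7 of 20 higher and 2 lower and the unfolded protein response 0.41 with 8 of 19 higher and 3 lower. Their adjusted p values with an estimated correlation were 0.191, 0.191 and 0.272. Neutrophils (0.44, 4 of 15 rose) and endothelial activation (0.53, 7 of 18 rose, 2 fell) were called, with adjusted p = 0.472 and adjusted p = 0.236 with an estimated correlation. Without imatinib 3 h replicate 2 both calls were lost (medians 0.21 and 0.40), and the neutrophil call also without imatinib 24 h replicate 2 (0.39).

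Interferon response (median 0.23, 5 of 23 genes rose, 1 fell), angiogenesis (0.26, 5 of 25) and imatinib target kinases (0.23, 3 of 10) passed with imatinib and not after PBS. Their adjusted p values with an estimated correlation were 0.558, 0.47 and 0.185. In the angiogenesis list 3 genes fell, and its call in camera was lost without imatinib 3 h replicate 1 (median 0.30, adjusted p = 0.0815) or imatinib 24 h replicate 1 (0.26, adjusted p = 0.0681). Cxcl10, an interferon-induced chemokine gene, rose by 2.28 ± 0.19, Kit, a stem cell factor receptor, by 1.84 ± 0.37 (adjusted p = 0.00664 in limma), the quinone reductase gene Nqo2, whose product binds imatinib, by 0.81 ± 0.15 and Pdgfra by 0.65 ± 0.19 (adjusted p = 0.0424). Kit and Nqo2 did not pass in limma without imatinib 3 h replicate 2 (1.70, adjusted p = 0.0614, and 0.53, 0.0556). Pdgfra did not pass in limma without imatinib 3 h replicates 1 (0.74, adjusted p = 0.106) or 2 (0.56, 0.212), imatinib 24 h replicates 1 (0.62, 0.108), 2 (0.63, 0.107) or 3 (0.70, 0.0726), PBS 3 h replicate 3 (0.65, 0.0514) or PBS 24 h replicate 2 (0.65, 0.0556). Pdgfrb had a value of 0.14 ± 0.19 (adjusted p = 0.729 in limma). Plat fell (-1.72 ± 0.27, adjusted p = 0.00172 in limma). The values of Ddr1, Ddr2, Pdgfc, Abl1, Abl2 and Csf1r, 0.25, 0.21, -0.05, -0.06, -0.06 and -0.07, did not pass.

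The lower lists with imatinib began with the glucocorticoid response, in which 14 of 15 genes fell, among them Fkbp5, a glucocorticoid-induced chaperone gene (-2.15 ± 0.19), with a median of -1.20 (adjusted p = 2.08e-14 with the preset and adjusted p = 0.102 with an estimated correlation). Immediate early genes had a median of -0.68 with 18 of 33 lower and 1 higher (adjusted p = 0.185 with an estimated correlation), and Wnt and barrier regulators a median of -0.56 with 12 of 20 lower, Fzd4 at -1.16 ± 0.19 (adjusted p = 0.185 with an estimated correlation). Transporters had a median of -0.51 with 8 of 17 lower (adjusted p = 0.236 with an estimated correlation), and endothelial markers a median of -0.24 with 5 of 18 lower (adjusted p = 0.47 with an estimated correlation). The p53 response (-0.35, 8 of 19 fell, 4 rose) and TGF-beta response (-0.19, 5 of 22 fell, 1 rose) followed, with adjusted p = 0.185 and adjusted p = 0.165 with an estimated correlation. Tight and adherens junctions (-0.15, 2 of 17 fell) and smooth muscle (-0.29, 2 of 12 fell) were called, with adjusted p = 0.438 and adjusted p = 0.58 with an estimated correlation. The junction call was lost without imatinib 3 h replicate 1 (-0.12) or replicate 2 (-0.18) or imatinib 24 h replicate 2 (-0.13). The smooth muscle call was lost without imatinib 3 h replicate 2 (-0.04), imatinib 24 h replicate 2 (-0.32) or replicate 3 (-0.25), its median being -0.66 without imatinib 3 h replicate 1. Pericyte markers, lower after PBS, had a median of -0.14 and no gene past the threshold (adjusted p = 0.4 in camera with the preset). Astrocyte (-0.34, adjusted p = 0.112 in camera) and erythroid markers (-0.22, adjusted p = 0.133) did not pass. Adjusted over the list alone, 17 genes were higher for cell cycle, 16 for cytokines, 11 for cholesterol synthesis, 10 each for the unfolded protein response and angiogenesis, 9 each for monocytes, oxidative phosphorylation and interferon response, 8 for endothelial activation, 7 for proteases, 6 each for glycolysis and complement, 4 each for neutrophils and border macrophages and 3 for kinases. Lower on that count were 23 immediate early, 14 glucocorticoid, 13 Wnt, 11 transporter, 9 p53, 8 endothelial, 6 junction, 6 TGF-beta and 2 smooth muscle genes. The mixed lists also had 6 lower for the unfolded protein response, 6 for angiogenesis, 2 each for interferon response, endothelial activation, proteases and glycolysis and 1 each for cytokines, complement and neutrophils, and 5 higher for p53, 1 for immediate early and 1 for TGF-beta.

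The comparison of imatinib with PBS at 24 h addressed the effect of the drug on vessels a day after MCAO (n = 3 in each group). No single gene passed. The lists of endothelial, barrier, basement membrane and pericyte genes had higher values in imatinib-treated mice and markers of monocytes lower values, while smooth muscle (median -0.01, 5 of 12 genes above 0) and perivascular fibroblast markers (0.05, 7 of 12) were not called. These list differences passed camera with the preset, and none passed with an estimated correlation (smallest adjusted p = 0.175). The lists share genes, and 8 of the 18 endothelial markers are also in other lists, such as those of junctions and angiogenesis. All 18 endothelial markers were above 0, with a median log2 difference of 0.25, and their mean signal was 10.52 ± 0.06 (SD) in imatinib and 10.26 ± 0.11 in PBS. In the monocyte list 9 of 11 markers were below 0, with a median of -0.49.

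In limma 0 of 30790 genes passed the Benjamini-Hochberg threshold, with 1879 at an unadjusted p under 0.05 (841 higher, 1038 lower) and a smallest adjusted p of 0.205. The groups did not overlap in 12.998% of genes, where chance gives 10%. Genes with the smallest p and lower values included LOC100038947, a signal-regulatory protein beta 1-like gene of the kind found in myeloid cells (-1.52 ± 0.19, adjusted p = 0.205 in limma), Ms4a4c (-0.84 ± 0.13, adjusted p = 0.302), Rnase6 (-0.80 ± 0.14) and Ocstamp (-0.68 ± 0.12). The signal of LOC100038947 in imatinib (3.22 ± 0.26, SD) lay below the 25th percentile of those arrays (3.83 to 3.85), so the size of its difference is uncertain. Those with higher values were Prrg1 (0.57 ± 0.09, adjusted p = 0.302 in limma), Ccbl1 (0.56 ± 0.10), Vwa1, a basement membrane protein gene (0.53 ± 0.10), Eps8l2 (0.67 ± 0.13) and Rec114 (0.45 ± 0.09). None of the imatinib target kinases passed: Abl2 had 0.31 ± 0.11 (adjusted p = 0.803 in limma), Pdgfrb 0.29 ± 0.17, Pdgfra 0.23 ± 0.17, Ddr2 0.08, Ddr1 0.05, Kit 0.01, Abl1 -0.02 and Csf1r -0.02. The ligand gene Pdgfc had -0.17 ± 0.17 and Plat 0.33 ± 0.24. On simulated data limma recovered 93.5% of 2-fold and 25% of 1.5-fold differences at this size.

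Camera with the preset called 16 of 43 lists, 12 higher and 4 lower with imatinib, and none with an estimated correlation. Fry in limma called 0 (smallest adjusted p = 0.0791). No member of any list passed over all genes. The endothelial list passed at an adjusted p of 2.66e-13 (adjusted p = 0.175 with an estimated correlation), with Eng, an endothelial co-receptor for TGF-beta, at 0.40 ± 0.10. All 20 Wnt and barrier regulators were above 0, with a median of 0.21 and Sox18 at 0.38 ± 0.11 (adjusted p = 3.88e-10 with the preset and adjusted p = 0.175 with an estimated correlation). In tight and adherens junctions 16 of 17 genes were above 0, with a median of 0.26 and Lsr, a protein of tricellular junctions, at 0.37 ± 0.11 (adjusted p = 8.19e-09 with the preset and adjusted p = 0.175 with an estimated correlation). All 17 transporters were above 0, with a median of 0.20 and Slc40a1 at 0.37 ± 0.09 (adjusted p = 7.72e-08 with the preset and adjusted p = 0.175 with an estimated correlation). Basement membrane genes had a median of 0.12, with Lamb2 at 0.43 ± 0.11 (adjusted p = 3.66e-05 with the preset and adjusted p = 0.175 with an estimated correlation), and 0.25 without PBS 24 h replicate 1. Angiogenesis genes had a median of 0.22, with Hey1 at 0.47 ± 0.12 (adjusted p = 4.81e-05 with the preset and adjusted p = 0.212 with an estimated correlation), and 0.12 without imatinib 24 h replicate 3. Pericyte markers had a median of 0.23 with 12 of 13 above 0, Rgs5 at 0.32 ± 0.10 (adjusted p = 7.12e-05 with the preset and adjusted p = 0.39 with an estimated correlation), and caveolae genes a median of 0.14 (adjusted p = 0.00381 with the preset and adjusted p = 0.251 with an estimated correlation), 0.23 without PBS 24 h replicate 1. Adjusted over the list alone, 2 basement membrane genes, and 1 each of the endothelial, transporter, angiogenesis and TGF-beta response lists were higher.

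Monocyte markers were lower as a list (adjusted p = 0.000521 with the preset and adjusted p = 0.286 with an estimated correlation), with Plac8 at -0.91 ± 0.25, and the median of -0.49 was -0.81 without PBS 24 h replicate 1, -0.16 without PBS 24 h replicate 3 and -0.25 without imatinib 24 h replicate 1. Erythroid markers moved with them, with a median of -0.23 and Hba-a2 at -0.63 ± 0.16 (adjusted p = 0.00126 with the preset and adjusted p = 0.175 with an estimated correlation). Neutrophils had a median of -0.17 (adjusted p = 0.0254 with the preset and adjusted p = 0.689 with an estimated correlation), and T and NK cells -0.08 with Gzma, a cytotoxic granule protease gene, at -0.69 ± 0.13 and a similarly low signal in imatinib (adjusted p = 0.0329 with the preset and adjusted p = 0.175 with an estimated correlation). Interferon response (0.11; adjusted p = 0.898 with an estimated correlation), TGF-beta response (0.08; adjusted p = 0.175), kinases (0.07; adjusted p = 0.175) and PDGF ligands and receptors (0.21; adjusted p = 0.175) were higher with the preset at adjusted p values of 0.0231, 0.0295, 0.041 and 0.041. The calls of these 4 and of the neutrophil and T and NK lists were lost without single arrays. The interferon call went without PBS 24 h replicate 1 (0.07), replicate 3 (0.02) or imatinib 24 h replicate 2 (0.01). Its median was 0.23 without PBS 24 h replicate 2 and 0.19 without imatinib 24 h replicate 1, with the call kept. TGF-beta was lost without PBS 24 h replicate 1 (0.07), replicate 2 (0.09) or imatinib 24 h replicate 1 (0.02), and PDGF without PBS 3 h replicate 3 (0.21), PBS 24 h replicates 1 (0.19) or 2 (0.18) or imatinib 24 h replicate 1 (0.02). The kinase call was lost without PBS 3 h replicate 3 (0.07), PBS 24 h replicates 1 (0.13) or 2 (0.11), or imatinib 24 h replicates 1 (0.09), 2 (0.19) or 3 (0.14), and its median was 0.12 without PBS 24 h replicate 3. The neutrophil call went without PBS 24 h replicate 3 (-0.08) or imatinib 24 h replicates 1 (-0.20) or 3 (-0.10), and that of T and NK cells without PBS 24 h replicate 2 (-0.10) or imatinib 24 h replicate 1 (-0.10), its median being -0.14 without PBS 24 h replicate 1. The scores of 11 of the 16 lists did not overlap between treatments, and those of transporters, angiogenesis, interferon, monocytes and neutrophils did. The exact permutation p of a score is at least 0.1, two-sided. Over the list alone 3 erythroid, 1 monocyte, 1 T and NK and 1 angiogenesis gene were lower. Of the 27 lists not called, the choroid plexus list (0.24, adjusted p = 0.309 in camera) was the nearest to the threshold.

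**Figure D4:**
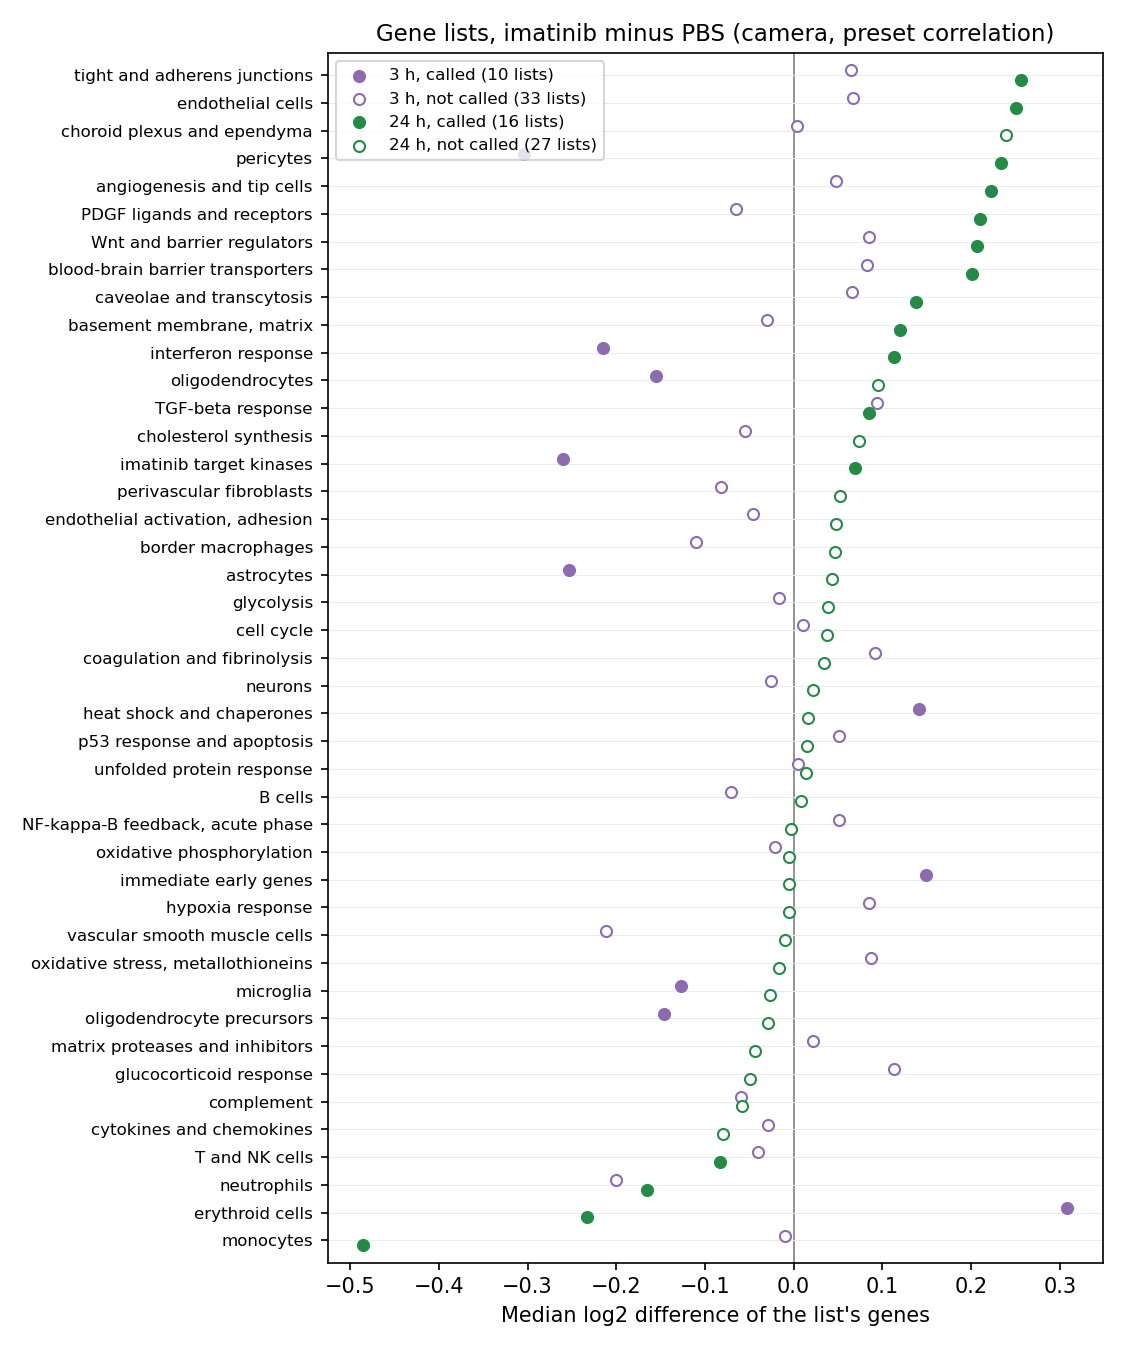
Median log2 difference (imatinib minus PBS) of the genes in each of 43 lists, at 3 h (purple) and 24 h (green); filled points passed camera at an adjusted p of 0.05 with the preset correlation, and none passed with an estimated correlation. The endothelial list has medians of 0.07 and 0.25, the pericyte list -0.30 and 0.23 and the erythroid list 0.31 and -0.23.

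At 3 h, 2 imatinib arrays were compared with 3 PBS arrays. No single gene passed. The lists with the largest medians in either direction were erythroid markers, pericyte markers and imatinib target kinases. Erythroid markers were higher with imatinib in 6 of 7 genes, with a median log2 difference of 0.31. Pericyte markers were lower in 13 of 13 genes, with a median of -0.30. The kinase list, which also holds the quinone reductase gene Nqo2, was lower in 9 of 10 genes, with a median of -0.26. Pdgfra, the PDGF receptor of fibroblasts and oligodendrocyte precursors, was 4.51 ± 0.12 in imatinib and 5.34 ± 0.33 in PBS (mean log2 signal ± SD), a difference of -0.83 ± 0.19 (SE, adjusted p = 0.679 in limma). Cldn6, a tight junction claudin, was 5.31 ± 0.16 in imatinib and 4.04 ± 0.09 in PBS, a difference of 1.27 ± 0.15 (adjusted p = 0.0564 in limma, 0.0435 with genes above the 25th percentile and 0.0493 with median centring).

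Limma found 0 genes past the Benjamini-Hochberg threshold and 1970 at an unadjusted p under 0.05 (992 higher, 978 lower). The groups did not overlap in 18.7% of genes, where chance gives 20%. After Cldn6, the smallest p among higher genes belonged to Atcayos (0.60 ± 0.12), Pou2f3 (0.58 ± 0.12), Slc22a13b-ps (1.37 ± 0.28) and Rnf32 (0.46 ± 0.10). Among lower genes it belonged to Arnt2 (-0.82 ± 0.13, adjusted p = 0.288 in limma), the cyclin gene Ccne1 (-0.70 ± 0.12), n-R5s62 (-0.84 ± 0.15), Ms4a4c (-0.81 ± 0.15, adjusted p = 0.435) and Cass4 (-0.70 ± 0.13). The other kinase values were -0.45 ± 0.19 for Pdgfrb, -0.28 for Ddr2, -0.26 for Kit, -0.22 for Ddr1, -0.19 for Abl1, -0.12 for Csf1r and 0.07 for Abl2, with -0.10 for Pdgfc and 0.25 ± 0.27 for Plat. On simulated data limma recovered 89.45% of 2-fold and 2.8% of 1.5-fold differences at this size.

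Camera with the preset called 10 lists, 7 lower and 3 higher with imatinib, and none with an estimated correlation (smallest adjusted p = 0.136). Pericytes passed at an adjusted p of 1.06e-06 (adjusted p = 0.492 with an estimated correlation), with Notch3 at -0.41 ± 0.13 and a median of -0.19 without PBS 3 h replicate 2. The kinase list passed at an adjusted p of 0.000271 (adjusted p = 0.136 with an estimated correlation) and was the only list called by fry (adjusted p = 0.0102). Of its 10 genes 4 are also in other lists, among them Pdgfrb (pericytes), Pdgfra (oligodendrocyte precursors) and Csf1r (microglia). In the kinase list 1 gene was lower adjusted over the list alone. Erythroid markers were higher beside them, with a median of 0.31, 6 of 7 genes above 0 and Hba-a2 at 0.71 ± 0.17 (3 higher adjusted over the list alone; adjusted p = 0.000998 with the preset and adjusted p = 0.425 with an estimated correlation). These 3 calls stood without each array in turn. Interferon response had a median of -0.21, with Cxcl10 at -0.59 ± 0.19 (adjusted p = 0.000271 with the preset and adjusted p = 0.711 with an estimated correlation), and microglia -0.13 (adjusted p = 0.00284 with the preset and adjusted p = 0.711 with an estimated correlation). Both calls were lost without PBS 3 h replicate 1 (medians -0.09 and -0.05), and the microglia median was -0.20 without PBS 3 h replicate 3. Immediate early genes were higher with a median of 0.15 (adjusted p = 0.000271 with the preset and adjusted p = 0.711 with an estimated correlation). The call was lost without PBS 3 h replicate 2 (0.06) or imatinib 3 h replicate 1 (0.15), with medians of 0.23 without PBS 3 h replicate 1 or imatinib 3 h replicate 2.

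Astrocyte (-0.25; adjusted p = 0.711 with an estimated correlation), oligodendrocyte (-0.15; adjusted p = 0.492) and oligodendrocyte precursor markers (-0.15; adjusted p = 0.425) were lower and heat shock genes higher (0.14; adjusted p = 0.711) with the preset, at adjusted p values of 0.0201, 0.0227, 0.0198 and 0.0397. Mobp, a myelin gene, had -0.73 ± 0.21 and the chaperone gene Hsph1 0.53 ± 0.40 (-0.27 without imatinib 3 h replicate 1 and 1.33 without replicate 2). Each of these calls was lost without single arrays: astrocytes without PBS 3 h replicates 1 (-0.16) or 2 (-0.18) or imatinib 3 h replicates 1 (-0.18) or 2 (-0.16). The oligodendrocyte call went without PBS 3 h replicate 2 (-0.14) or imatinib 3 h replicates 1 (-0.30) or 2 (-0.12), and that of precursors without imatinib 3 h replicate 1 (-0.05). Heat shock lost its call without PBS 3 h replicates 1 (0.11) or 2 (0.15) or imatinib 3 h replicate 1 (-0.02, the other direction), and its median was 0.28 without imatinib 3 h replicate 2. Adjusted over the list alone, 2 precursor genes were lower. The scores of 6 of the 10 lists did not overlap between treatments, and those of immediate early, heat shock, astrocyte and microglia genes did. No score has an exact permutation p under 0.1, two-sided. Of the 33 lists not called, Wnt and barrier regulators (0.09, adjusted p = 0.0536 in camera) were the nearest to the threshold, and endothelial markers had a median of 0.07 (adjusted p = 0.0913).

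**Figure D5:**
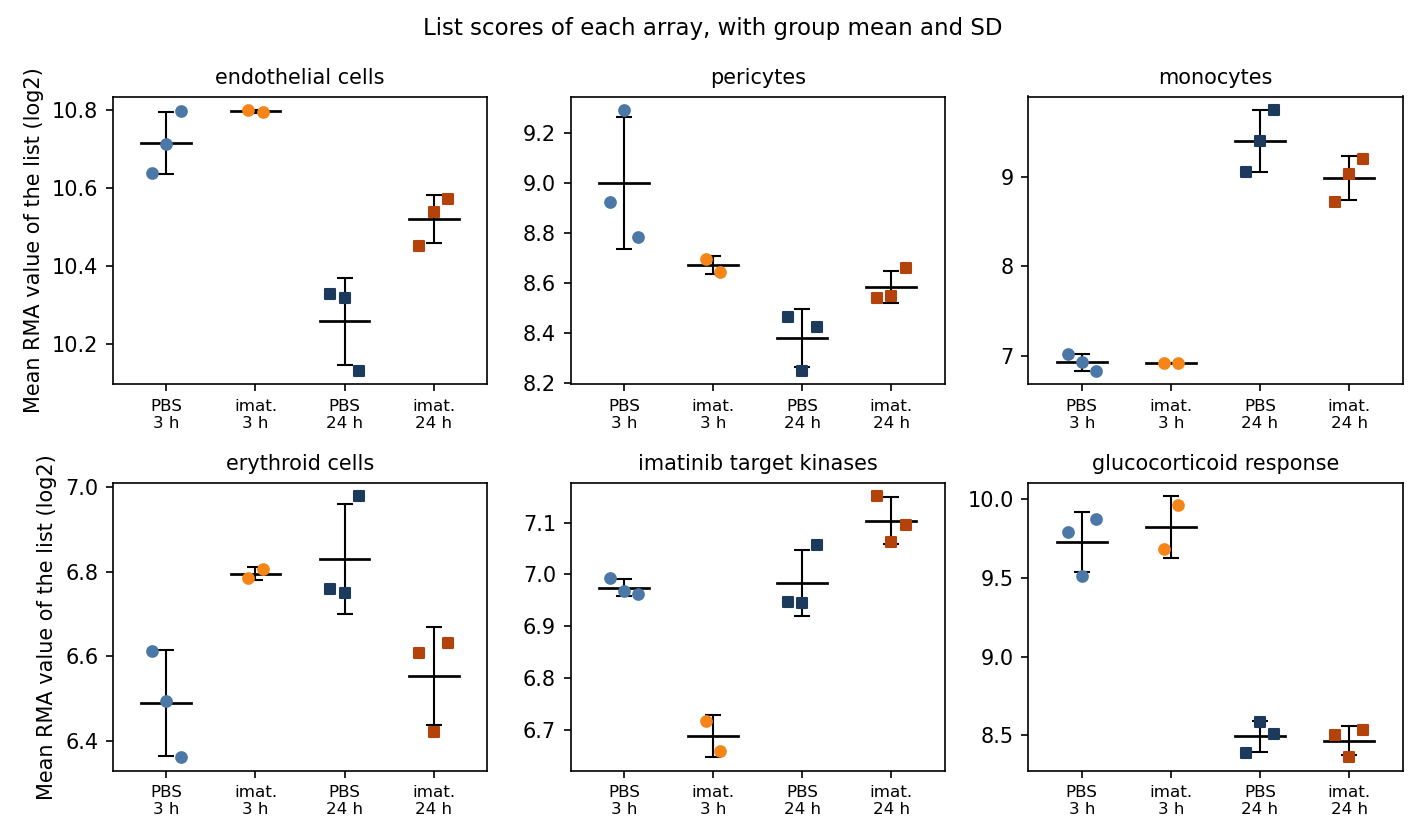
Mean RMA value (log2) of the genes of 6 lists on each array; points are arrays, lines the group mean and bars 1 SD (n = 3, 2, 3 and 3). The pericyte score averages 9.002 in PBS and 8.67 in imatinib at 3 h, and 8.38 and 8.58 at 24 h; the endothelial score averages 10.26 in PBS and 10.52 in imatinib at 24 h.

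The last comparison asked whether the difference between imatinib and PBS changed from 3 h to 24 h. Pericyte markers had the largest shift towards higher values, from a median of -0.30 at 3 h to 0.23 at 24 h, and erythroid markers the largest in the opposite direction, from 0.31 to -0.23. Pdgfra, whose differences of -0.83 and 0.23 passed at neither time, had a difference of differences of 1.06 ± 0.25 (log2 ± SE, adjusted p = 0.802 in limma) and Pdgfrb of 0.74 ± 0.26 (adjusted p = 0.868 in limma). Across genes the imatinib differences at both times correlated with a Pearson's r of 0.0398 and a Spearman's rho of 0.0512, and the r was -0.0204 to 0.0712 with 1 array left out.

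No gene passed in limma after the Benjamini-Hochberg correction, with 1690 at an unadjusted p under 0.05 (716 higher, 974 lower) and a smallest adjusted p of 0.371. On simulated data limma recovered 51.9% of 2-fold and 98.65% of 4-fold differences here. The smallest p belonged to Cldn6 (-1.47 ± 0.20), Hba-a2 (-1.34 ± 0.23), Hbb-b2 (-1.18 ± 0.21), Atcayos (-0.79 ± 0.16) and Dgat2 (-0.70 ± 0.14) among negative values and to Arnt2 (1.13 ± 0.17), Cyp2d13 (1.004 ± 0.19), Nkain2 (0.87 ± 0.17), the chloride channel gene Ano1 (0.77 ± 0.17) and AU041133 (1.01 ± 0.22) among positive values. The other values were 0.37 for Ddr2, 0.27 for Kit, 0.27 for Ddr1, 0.24 for Abl2, 0.17 for Abl1, 0.10 for Csf1r, -0.08 for Pdgfc and 0.08 ± 0.37 for Plat. Camera with the preset called 18 lists, 15 higher and 3 lower, and none with an estimated correlation (smallest adjusted p = 0.0627). In the pericyte list 13 of 13 genes were above 0, with a median of 0.54 (adjusted p = 1.33e-10 with the preset, adjusted p = 0.28 with an estimated correlation and 0.25 in fry), and 6 were higher adjusted over the list alone. In the kinase list 10 of 10 were above 0, with a median of 0.31 (adjusted p = 1.33e-05 with the preset, adjusted p = 0.0627 with an estimated correlation and 0.00446 in fry). Erythroid markers had a median of -0.62 (adjusted p = 1.33e-05 with the preset, adjusted p = 0.166 with an estimated correlation and 0.0475 in fry), and 4 were lower adjusted over the list alone.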

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

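Of the tests in this part, those of other splits for the lists over time in PBS, of a single array for the monocyte list, of fewer leukocytes, of less advanced change, of fewer other cells at 3 h and of the endothelial share at 24 h were chosen after the result was seen.

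By camera with the preset, the imatinib difference shifted between 3 h and 24 h relative to other genes in 18 lists. With an estimated correlation it did in 0 (smallest adjusted p = 0.0627). Fry, which does not compare a list with other genes, called 2, kinases (adjusted p = 0.00446) and erythroid cells (0.0475). Other splits of the arrays were not tried for this contrast. Among the 18 lists the largest median shifts were those of erythroid cells (-0.62, camera adjusted p = 1.33e-05 with the preset and 0.166 with an estimated correlation), pericytes (0.54, 1.33e-10 and 0.28), monocytes (-0.45, 0.0165 and 0.658), interferon response (0.39, 5.21e-06 and 0.588) and imatinib target kinases (0.31, 1.33e-05 and 0.0627). Then came oligodendrocytes (0.24, camera adjusted p = 0.00732 and 0.294), basement membrane (0.22, 0.00499 and 0.294), junctions (0.20, 0.00214 and 0.388), endothelial cells (0.18, 0.000483 and 0.588), immediate early genes (-0.18, 0.00776 and 0.766), astrocytes (0.16, 0.0251 and 0.766) and PDGF ligands and receptors (0.15, 0.00661 and 0.166). The smallest were Wnt regulators (0.13, camera adjusted p = 0.016 and 0.697), angiogenesis (0.13, 0.0173 and 0.658), cholesterol synthesis (0.12, 0.0417 and 0.775), oligodendrocyte precursors (0.12, 0.016 and 0.28), transporters (0.12, 0.0184 and 0.766) and microglia (0.11, 0.0465 and 0.788).

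The calls of pericytes, interferon response, kinases, junctions, endothelial cells and erythroid cells stood without each array, though the median was 0.20 for interferon without PBS 3 h replicate 1 and 0.25 without PBS 24 h replicate 3, 0.12 for junctions without PBS 3 h replicate 3, and 0.12 and 0.11 for endothelial cells without PBS 3 h replicate 3 or PBS 24 h replicate 3. The other 12 were lost without at least 1 array. Monocytes went without PBS 3 h replicate 3 (-0.32), imatinib 3 h replicate 2 (-0.33), PBS 24 h replicates 2 (-0.36) or 3 (-0.15) or imatinib 24 h replicate 1 (-0.20), and immediate early genes without PBS 3 h replicate 2 (-0.11), imatinib 3 h replicate 1 (-0.12) or PBS 24 h replicate 3 (-0.14). Wnt regulators went without PBS 3 h replicate 3 (0.09), imatinib 3 h replicate 2 (0.13) or PBS 24 h replicate 3 (0.10), and transporters without PBS 3 h replicate 3 (0.09), imatinib 3 h replicate 2 (0.11), PBS 24 h replicates 1 (0.07) or 3 (0.08) or imatinib 24 h replicate 2 (0.08). Basement membrane went without imatinib 3 h replicate 1 (0.13), PDGF without imatinib 3 h replicate 1 (0.18) or imatinib 24 h replicate 1 (0.12), oligodendrocytes without imatinib 24 h replicate 1 (0.04) and precursors without imatinib 3 h replicate 1 (0.19) or PBS 24 h replicate 2 (0.09). Angiogenesis went without PBS 3 h replicate 3 (0.13), imatinib 3 h replicate 1 (0.14), PBS 24 h replicates 2 (0.19) or 3 (0.11) or imatinib 24 h replicate 1 (0.13), and cholesterol synthesis without PBS 3 h replicates 1 (0.08) or 2 (0.07), imatinib 3 h replicates 1 (0.07) or 2 (0.15), PBS 24 h replicate 2 (0.05) or imatinib 24 h replicate 3 (0.06). Astrocytes went without PBS 3 h replicates 1 (0.12) or 2 (0.13), imatinib 3 h replicates 1 (0.19) or 2 (0.19), PBS 24 h replicate 2 (0.05) or imatinib 24 h replicate 1 (0.11). Microglia went without PBS 3 h replicates 1 (0.02) or 2 (0.11), imatinib 3 h replicates 1 (0.11) or 2 (0.08), PBS 24 h replicates 1 (0.09) or 2 (0.10) or imatinib 24 h replicates 1 (0.11) or 2 (0.06).

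Other medians moved over 1.5 times with the call kept. Precursors were at 0.23 without PBS 3 h replicate 2, 0.24 without imatinib 3 h replicate 2, 0.21 without PBS 24 h replicate 3, 0.27 without imatinib 24 h replicate 2 and 0.03 without imatinib 24 h replicate 3. Oligodendrocytes were at 0.14 without PBS 3 h replicate 3 or PBS 24 h replicate 1, 0.37 without imatinib 3 h replicate 1 and 0.08 without imatinib 3 h replicate 2. PDGF was at 0.23 without PBS 3 h replicate 1, 0.26 without PBS 3 h replicate 3 and 0.32 without imatinib 24 h replicate 2, and astrocytes at 0.27, 0.25 and 0.30 without PBS 3 h replicate 3, PBS 24 h replicate 1 and imatinib 24 h replicate 2. Transporters were at 0.23 without PBS 24 h replicate 2 and 0.21 without imatinib 24 h replicate 1, angiogenesis at 0.21 without PBS 24 h replicate 1 and 0.22 without imatinib 24 h replicate 2. Without PBS 24 h replicate 1 cholesterol synthesis was at 0.19, without PBS 24 h replicate 3 basement membrane at 0.14 and without PBS 3 h replicate 3 microglia at 0.20.

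Vessel and barrier lists were higher and monocyte markers lower with imatinib at 24 h by camera with the preset, all lost with an estimated correlation (adjusted p at least 0.175, monocytes 0.286) and with no gene past the threshold, and a direct effect of the drug on the vessels stays open as the biological explanation, untested. Endothelial markers differed about as much (median 0.25) as junction (0.26), Wnt (0.21) and transporter genes (0.20). These medians do not tell raised barrier genes from a higher share of endothelial RNA in the fragments, which was not tested. Smooth muscle and perivascular fibroblast markers were not called. A single array as the cause is argued against for the endothelial list, whose median was at least 0.195 without any of the 24 h arrays, and stays open for the monocyte list, whose median of -0.49 was -0.161 without PBS 24 h replicate 3 and -0.25 without imatinib 24 h replicate 1. Fewer leukocytes in the fragments may have raised all resident cell types alike, and while the parenchymal difference of 0.0327 ± 0.0761 (SE), against 0.261 ± 0.0655 for the endothelial score, goes against it, the gap of 0.229 ± 0.130 lies within 2 SE and leaves it open. Of the 11 monocyte markers 2 are in other lists and 7 lie above the median gene in PBS at 3 h, and the most abundant, Fn1, was 11.7 in PBS and 11.8 in imatinib at 24 h. Vessels less advanced along the time course could also account for it, and the correlation of the imatinib effect with the time change was 0.0274, which does not decide, since both share the imatinib 24 h arrays and 100 simulations without an imatinib effect gave a mean of 0.193 and -0.172 to 0.645, 13 at or below the value found. The spread of array signals went with treatment at 24 h too. The imatinib arrays had lower medians (5.172 to 5.182 against 5.203 to 5.221 in PBS) and higher 75th percentiles (7.041 to 7.061 against 7.025 to 7.039). Its part in these list differences was not tested beyond cyclic loess and median centring.

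Pericyte markers were lower with imatinib at 3 h and higher at 24 h by camera with the preset, lost with an estimated correlation (adjusted p = 0.492 and 0.39), and a drug effect on pericytes stays open, untested. A single array is argued against by the lowest median of the difference, 0.417, without any 1 array. Fewer cells other than endothelial cells in the imatinib 3 h fragments may explain the lower values at 3 h. The pericyte score differed by -0.331 ± 0.145 (SE). The scores of 6 other cell types were lower too, from -0.257 ± 0.121 for oligodendrocytes to -0.0743 ± 0.0819 for neurons. The gap between pericytes and these types was at most 1.71 SE (0.177 ± 0.103 for perivascular fibroblasts), which leaves this explanation open. All 13 pericyte markers lie above the median gene in PBS at 3 h, 2 are in other lists, and the most abundant, Rgs5, was 12.1 in PBS and 11.9 in imatinib at 3 h. Erythroid markers moved the opposite way at both times.

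Glucocorticoid and immediate early genes were lower at 24 h than at 3 h in both treatments by camera with the preset, lost with an estimated correlation (adjusted p = 0.0716 and 0.246 in PBS, 0.102 and 0.185 in imatinib), and stress of the operation wearing off may be a biological explanation, untested, as vessels without occlusion were not analysed here. A different time of day at sampling would part clock genes of opposite phase, but both sides had medians of the same sign in PBS (-0.43 and -0.70). This argues against a shift large enough to part them. Of the 12 clock genes 2 passed in PBS, which cannot exclude a smaller shift, as SE reached 0.48 (Ciart). A lower share of endothelial RNA at 24 h as the whole cause for the glucocorticoid list is argued against because its score difference lay below the endothelial one, by -0.779 ± 0.135 (SE) in PBS and -1.08 ± 0.15 in imatinib, and for immediate early genes this was not tested.

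Other splits of the same arrays count the calls made when the real groups are mixed. At 24 h and over time in PBS, each other split keeps part of the real difference and moves the rest into the spread. This holds gene counts down, and list calls may carry a real difference. These splits therefore do not show how many calls arise without an effect. At 24 h, the 10 splits of the imatinib and PBS arrays are too few for a share under 0.05, and limma found 0 genes in the real split and in all 10, at most 0 in any other. Camera with the preset called 16 lists in the real split, the only 1 of the 10 with as many, and up to 15 in the others. For the time course in PBS the splits are again too few, with 5119 genes in limma in the real split, the only 1 with as many, and at most 0 in the others, and 24 lists in camera with the preset in the real split and up to 18 in the others. For a treatment effect common to both times, 6 of 100 splits gave as many genes as the 1 found (highest other 1) and 10 of 100 as many lists as the 14 found (highest other 20), so chance is not excluded.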

How the results depend on the processing

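Of the alternatives here, the fit without PBS 3 h replicate 1 and PBS 24 h replicate 3 together and the treatment effect common to both times were chosen after the data were seen. Of 1817 values of the 92 list calls under 20 alternatives, which leave out the exchange of identical tables, 1637 kept direction and side of the threshold, 179 lost the call and 1 turned, heat shock at 3 h (-0.022 to 0.28 with 1 array left out). With the estimated correlation all 92 were lost and the counts were 0 lists at 3 h, 0 at 24 h, 0 over time in PBS, 0 over time in imatinib and 0 in the interaction. The alternative allows for genes of a list that vary together. Over all genes the naming rule allows, 4306 of 4595 values of the 230 past the threshold stayed and 289 did not pass, and of 3804 values of the 195 not past it, 3744 stayed, 28 passed and 32 changed sign. The report describes part of these genes. At 3 h the counts in limma were 2 genes above the 25th percentile (Cldn6 and Olfr116), 2 with median centring (the same), 2 at an adjusted p under 0.1 and 1970 at an unadjusted p under 0.05 (6.40% of genes), and 0 to 4 with 1 array left out (4 without imatinib 3 h replicate 2). At 24 h the counts were 1879 unadjusted and 0 to 1 (1 without PBS 24 h replicate 1), in the interaction 1690 and 0 to 2 (2 without imatinib 3 h replicate 2). Over time they were 881 at 2-fold or more and 8401 unadjusted in PBS, and 815 and 7685 in imatinib, with 2274 to 4233 without 1 array. Lists called at 3 h were 6 above the median gene, 6 without these 2 PBS arrays and 6 to 18 with 1 array left out (6 without PBS 3 h replicate 1, 18 without PBS 3 h replicate 3). At 24 h they were 10 above the median gene and 10 with cyclic loess, over time in imatinib 14 above the median gene, and in the interaction 8 above the median gene and 11 to 18 with 1 array left out. Above the median gene fewer genes were tested, so the comparison set is smaller there. With cyclic loess and without the 2 PBS arrays all 30790 genes were tested, so this does not apply to them. The imatinib 24 h arrays had lower 25th percentiles (3.830 to 3.845) than the PBS 24 h arrays (3.871 to 3.881). Their 75th percentiles were higher (7.041 to 7.061 against 7.025 to 7.039), so the spread of signals went with treatment at 24 h. Whether this or anything else caused these changes in the counts was not tested. The correlation of the time changes was 0.891 above the median gene and 0.728 to 0.782 with 1 array left out. Where 1 array is left in a group, it is assumed to vary like the others, and the number of arrays limits all of these.

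Some values of genes not past the threshold changed sign. At 3 h Hsph1 was -0.27 to 1.33 with 1 array left out, Abl2 -0.0096 without the 2 PBS arrays (-0.0096 to 0.12 with 1 array left out) and Pdgfc -0.28 to 0.083. At 24 h Kit was -0.0093 with cyclic loess and -0.041 with array weights (-0.41 to 0.33), Abl1 0.015 with median centring (-0.0449 to 0.010), Csf1r 0.020 with centring and 0.028 without the 2 PBS arrays (-0.074 to 0.029), Ddr1 -0.071 to 0.15 and Ddr2 -0.051 to 0.17. Over time in PBS Ddr1 was -0.12 to 0.099 and Pdgfc -0.16 to 0.20, in imatinib Abl1 -0.18 to 0.058 and Pdgfc -0.17 to 0.050. In the interaction Kit was -0.15 to 0.59, Pdgfc -0.26 to 0.11 and Plat -0.23 to 0.35. The cause was not tested.

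Whether the replicate numbers pair the arrays stays undecided. Arrays with the same number had a mean correlation of residuals of 0.0115 (-0.0373 to 0.0577) and others -0.00574 (-0.0577 to 0.0482). Residuals sum to 0 within each group, which ties these means to each other, so their small size cannot exclude pairing. Of 11 arrays, 7 correlated best with arrays of their own number. With the replicate numbers as a block, limma called 0 genes at 3 h, 0 at 24 h, 4844 over time in PBS, 3379 in imatinib and 0 in the interaction. Over time, Pdgfrb (adjusted p = 0.0524) and Csf1 (0.0595) in PBS and Pdgfra (0.0760) and Hba-a2 (0.0594) in imatinib then did not pass in limma. With only the groups compared, Pdgfrb (adjusted p = 0.0822) and Csf1 (0.115) did not pass in PBS in limma.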

Other observations

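Genes that make ribosomes rose together between 3 h and 24 h. In PBS 23 of 24 ribosome biogenesis genes rose, and in imatinib 22, with medians of 0.92 and 0.86. In PBS Utp20, which processes ribosomal RNA, rose by 1.70 ± 0.11 (log2 ± SE, adjusted p = 4.1e-06 in limma) and Nhp2 by 1.64 ± 0.14, and in imatinib they rose by 1.57 ± 0.12 and 1.60 ± 0.15. This and the following 3 lists were chosen after a first look at the genes past the threshold, and genes seen there were left out (3 and 5 from 2 of the lists, 0 from this list and the synthetases). The camera adjusted p over these 4 lists was 9.41e-25 in PBS with the preset and 0.0097 with an estimated correlation, and 9.44e-24 and 0.0086 in imatinib. As the lists were chosen from the same data, and p was adjusted over 4 lists only, these p values cannot be compared with those of the 43 fixed lists.

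Genes of purine, pyrimidine and polyamine synthesis followed, with 11 of 13 higher in PBS and 9 in imatinib (medians 0.69 and 0.76; camera adjusted p = 0.0097 and 0.0086 with an estimated correlation; 3 genes left out). Umps, which makes pyrimidine nucleotides, rose by 1.53 ± 0.12 in PBS, and Gart by 1.35 ± 0.15. Of 19 aminoacyl-tRNA synthetase genes 15 rose in PBS and 17 in imatinib (medians 0.80 and 0.70; camera adjusted p = 0.0191 and 0.017 with an estimated correlation), with Farsb at 1.12 ± 0.12 in PBS. Fc and pattern recognition receptors, with 5 genes left out, had medians of 0.47 and 0.46 (camera adjusted p = 0.0853 and 0.105 with an estimated correlation), with 8 and 7 of 15 higher, and Cd36, a scavenger receptor, rose by 2.42 ± 0.19 in PBS. With imatinib at 24 h the Fc receptors (-0.16) and ribosome biogenesis (-0.09) had a camera adjusted p of 0.0064 with the preset and 0.471 with an estimated correlation, and no gene passed in limma. The other values with imatinib lay between -0.08 and 0.01 at 3 h, and none of the 4 lists passed in the interaction.

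For a treatment effect common to both times, Ms4a4c, a membrane protein gene of leukocytes, was lower with imatinib by -0.82 (adjusted p = 0.0389 in limma), and 2137 genes had an unadjusted p under 0.05. A gene passed without PBS 3 h replicate 1 (1 gene) or replicate 2 (1 gene), and 0 passed without any 1 of the other 9 arrays. This fit was chosen after the data were seen. Its means were 5.19 ± 0.24 (SD) in PBS and 4.38 ± 0.07 in imatinib at 3 h, and 7.41 ± 0.14 and 6.58 ± 0.13 at 24 h.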
